A study of Mus musculus with 48 samples.

How the data were processed

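The data are 48 libraries from mouse liver: ribosome profiling, which sequences the mRNA fragments shielded by ribosomes (footprints), and total RNA sequencing. Per the labels, male C57BL/6JRj mice aged 11 to 12 weeks were entrained for 2 weeks to 12 h of light and 12 h of darkness. Livers were taken at 12 time points spaced 2 h apart, named by zeitgeber time (ZT, hours after lights on). Per the labels' protocols, each of the 2 replicates of a time point was a lysate pooled from the livers of 2 mice, and the same lysate served both assays, so that 24 pools from 48 mice gave 24 footprint and 24 total RNA libraries. Replicates are therefore separate pools of different animals. Per the labels' protocols, livers were lysed with cycloheximide, which halts elongating ribosomes of the cytosol. By the same protocols, footprints were made with RNase I and recovered on size exclusion columns, and ribosomal RNA was removed with Ribo-Zero.

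The values are RPKM (reads scaled to gene length and library size) per Ensembl gene, as deposited, in 1 table per library. Per the submitters' processing notes, the tools named were CASAVA 1.82, cutadapt, Bowtie2 2.2.1, TopHat, TopHat2 2.0.11, Cufflinks 2.2.1 and edgeR, and the genome builds GRCm38.p2 and mm10. The role and order of these tools, the gene models, the counting of reads that match several places and the scaling between libraries are not given in the sources used here. Upper quartiles lay between 21.7 and 22.7 RPKM in footprints and between 26.6 and 27.9 in total RNA, so the deposited values were close to a common scale within each assay. An absolute change of all transcripts or all footprints together would not be seen on such a scale, and translation efficiency (the footprint to total RNA ratio) is relative between genes. Reads shared with near-identical copies, such as ferritin pseudogenes, histone H4 genes, alpha globins and nuclear copies of mitochondrial genes, could be split or lost by the counting. Those genes are reported as uncertain. Copies of other genes, ribosomal proteins and translation factors among them, were not examined, so their values are not free of this limit.

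Footprint libraries listed 10980 genes and total RNA libraries 11155 genes, with 10829 in both and 11306 in either. Symbols and coordinates came from the GENCODE M21 annotation of GRCm38, by Ensembl ID. It named 11242 of the IDs and left 64 without a name. RPKM times coding length came in whole multiples of a step for 76.4% to 85.6% of low values in footprints and for 74.6% to 85.5% in total RNA, at a tolerance of 0.04 of a step, where chance gives 8.0%. The step gave each library's approximate depth in reads on the listed genes. It was 13.9 to 43.0 M reads for footprints, with a median of 17.9 M, and 3.86 to 23.8 M reads for total RNA, with a median of 11.8 M. The shallowest library was total RNA of ZT18 replicate 2, with 112 genes at 0. No pair of libraries held identical values.

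Tests used R 4.3.3 with limma 3.58.1, and tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The 9445 genes with a mean of at least 1 RPKM in both assays were tested on log2(RPKM + 0.1). A cosine and a sine with a period of 24 h were fitted to the 24 libraries of an assay with limma, with a mean-variance trend, and both terms were tested by a moderated F test with Benjamini-Hochberg adjustment. A gene was called rhythmic at an adjusted p under 0.05 with a fitted peak-to-trough fold of at least 1.5. Folds are on the log2(RPKM + 0.1) scale, which understates the change of low genes, and brackets after folds give 95% intervals. Rhythmic translation efficiency was tested as the interaction of assay and harmonic over the 48 libraries, called at an adjusted p under 0.05. Peak delay and amplitude ratio were medians over genes called in both assays, with p from 100 draws (the real one included) that swapped assays within pools.

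The pairing of footprint and total RNA libraries comes from the shared lysate. As a check, deviations of both assays from their time point means were correlated across genes, and r lay between 0.16 and 0.683, above 0.1 at 12 of 12 time points. The paired fit, on the log2 ratio of each pool, is printed beside the main efficiency results. Replicate numbers say nothing across time points.

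A set of 31 gene lists, covering the clock and its outputs, the translation machinery, metabolism, stress, mitochondria, secreted proteins and other cell types, was fixed before the data were examined. So were the tests, the thresholds and the rule for naming genes. Of these lists, 30 had at least 3 tested members. A list's rhythm was the 24 h harmonic of the mean of its gene-centred members in 24 libraries or pools, with a two-sided permutation test (100000 shuffles of time, smallest possible p 1e-05) and adjustment over lists. A list's mean efficiency was compared with other genes by camera in limma, with a preset correlation of 0.01 and also with an estimated one. Within a list, genes called over all 9445 genes are given with the number adjusted over the list alone. Some list members by name were not analysed here. The text names the measured core clock genes and the 10 called genes with the largest range per comparison whose replicate series peaked within 3 h. It also names up to 4 members per list with the smallest adjusted p, the 10 smallest interaction p among genes rhythmic in footprints and efficiency alone, the 5 highest and 5 lowest genes in mean efficiency, and 10 genes fixed by name. Some genes that this rule takes are not reported here.

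Rhythms were simulated among 9445 genes and scored at an adjusted p under 0.05, without the minimum fold of 1.5. So scored, the total RNA test recovered 74.6% of 1.5-fold and 95.5% of 2-fold rhythms with 6.3% false calls. The footprint test recovered 77.6% and 95.5% with 5.2% false. The efficiency test recovered 64.2% of 1.5-fold and 82.1% of 2-fold with 4.8% false, with noise drawn apart for each assay as if no lysate were shared. Recovery with the minimum fold, which total RNA and footprint calls require, was not simulated. Noise was also drawn apart for each gene, while some groups of genes moved together between pools in the data. The shares of false calls may therefore not carry over to these data. In 20 draws of 30 simulated lists, the list tests recovered 65% of 1.5-fold footprint rhythms, 88.5% of 1.5-fold efficiency rhythms and 96% of level shifts of 1 log2. False calls per draw were 0.15, 0.6 and 0.35.

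Alternatives chosen before the data were examined were pseudocounts of 1 and 0.01, other filters on low values, median centring, other thresholds, time as a factor, limma without the trend, replicate and pool blocks, list medians and leaving out each pool. Those added after seeing the data were voom weights on recovered reads, thinning to the lowest depth of an assay, leaving out the shallowest library, leaving out 6 pools with pancreatic transcripts, removing trends on coding length and GC content, and combinations of the pool block with these or with a minimum fold of 1.5.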

Results

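Footprint and total RNA libraries were compared over a day in mouse liver, with 2 pools of 2 livers at each of 12 time points and both assays made from each of the 24 lysate pools. Ribosome footprints report how many ribosomes sit on a transcript, and total RNA reports the transcript itself. Footprint libraries held about 13.9 to 43.0 M reads on the listed genes and total RNA libraries about 3.86 to 23.8 M reads. Total RNA libraries of ZT18 were the shallowest, with a mean of 5.20 M reads. The lights were on from ZT0 to ZT12. The design asks which transcripts cycle, which are translated in a cycle, and whether translation efficiency itself cycles.

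Transcripts of the molecular clock cycled widely in total RNA, with Ciart and Dbp the widest of the called genes. Ciart, a repressor of the clock, cycled 85.8-fold (95% interval 46.5 to 158.3), and Dbp, an output transcription factor, cycled 57.0-fold (33.2 to 98.1) with a peak at ZT10.8. Nr1d1, the nuclear receptor that represses Arntl, cycled 38.8-fold with a peak at ZT8.1, and Arntl, the activating partner of Clock, cycled 25.2-fold with a peak at ZT23.1 (adjusted p = 2.34e-09, limma). In RPKM, Arntl (chromosome 7, 113207465 to 113314126, GRCm38) stood at 19.7 ± 0.195 (SD, n = 2) at ZT2 and 0.587 ± 0.0591 at ZT12. Dbp (chromosome 7, 45705088 to 45710203) stood at 76.8 ± 5.55 at ZT10 and 0.656 ± 0.0439 at ZT0. The period genes followed in the dark, Per1 with 13.1-fold at ZT13.8 and Per2 with 8.71-fold at ZT15.6, and Cry1 came later with 6.47-fold at ZT20.7. Nr1d2 cycled 9.47-fold, Tef 6.49-fold, Nfil3 4.27-fold, Bhlhe40 3.05-fold, Hlf 2.26-fold, Clock 2.04-fold and Cry2 1.67-fold. Rora, at 1.25-fold with an adjusted p of 0.0181, missed the minimum fold. In all, 15 of 16 tested core clock genes were called, and 15 adjusted over the list alone, each over the 24 libraries.

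**Figure D1:**
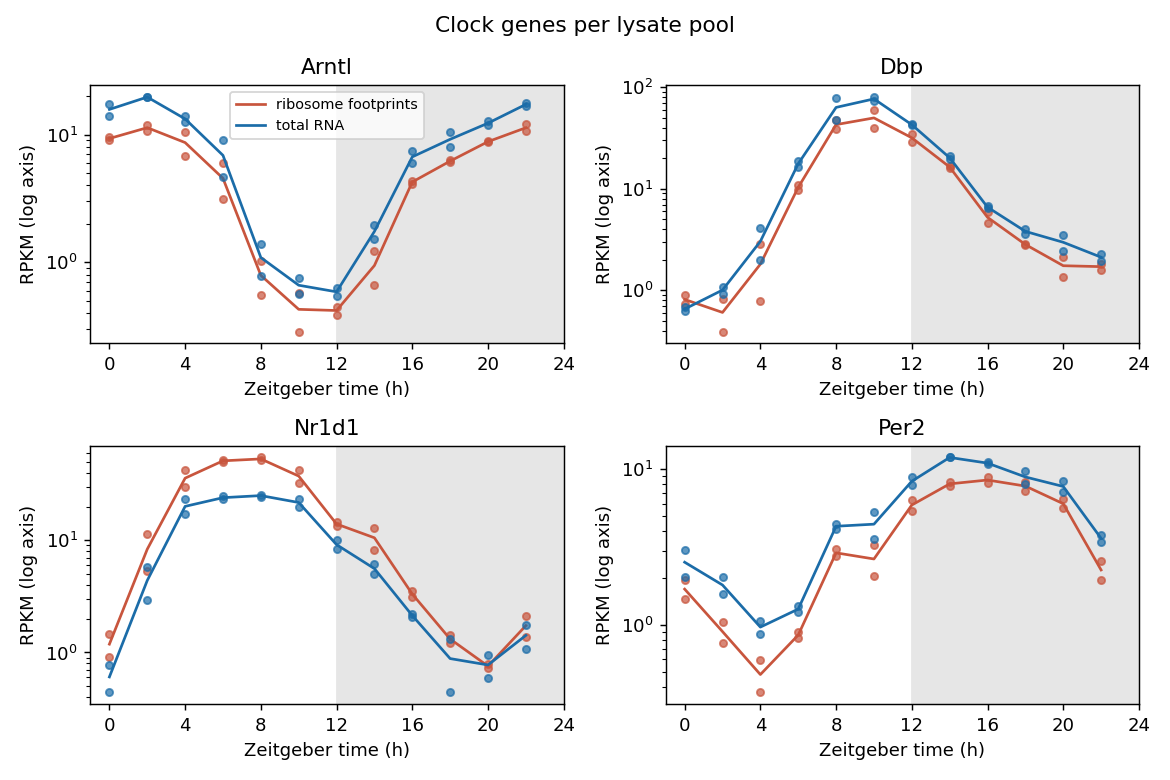
RPKM (log axis) of Arntl, Dbp, Nr1d1 and Per2 against zeitgeber time in h, with a point per lysate pool and lines through the means of the 2 pools, and darkness shaded. Arntl is highest at ZT2 and lowest at ZT12 in both assays, and Dbp is highest at ZT10.

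Clock outputs and several metabolic programs cycled in total RNA beside the clock. Of 17 tested clock-controlled outputs, 16 were called (16 adjusted over the list alone), among them the fatty acid elongase Elovl3 with 22.4-fold at ZT0.6, Noct with 10.9-fold, and Nampt, the enzyme that limits NAD salvage, with 3.97-fold. The G-protein regulator Rgs16 cycled 33.1-fold. Glucocorticoid targets moved as a list by 2.55-fold (1.99 to 3.27) around ZT13.5, with 10 of 14 called, among them Lpin1 with 8.02-fold and Fkbp5 with 5.77-fold. Heat shock proteins moved by 1.78-fold around ZT18.1, with 12 of 17 called, among them the small heat shock protein Hspb1 with 3.28-fold. Fatty acid synthesis moved by 1.53-fold around ZT17.2, with 12 of 15 called, among them Thrsp with 8.93-fold, Elovl6 with 3.24-fold and Acly with 2.27-fold. Xenobiotic metabolism moved by 1.40-fold around ZT16.2 with 9 of 21 called, led by Cyp2a5 with 3.94-fold and Por, the electron donor of cytochromes P450, with 3.70-fold. For these lists the count adjusted over the list alone equalled that over all genes. The lists share members and are not separate evidence throughout. Lpin1 of the glucocorticoid targets, Por and Alas1 of xenobiotic metabolism and Gys2 of glucose metabolism are also clock-controlled outputs. Per1 is both a core clock gene and a glucocorticoid target.

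Over all 9445 genes, 1494 (15.8%) were called rhythmic in total RNA, 84 of them by at least 4-fold, with a median fold of 1.77. Peaks fell in the light for 733 genes and in the dark for 761. Among 30 lists, 14 cycled in total RNA, those above at permutation adjusted p of 7.5e-05 for the clock, its outputs, glucocorticoid targets and xenobiotic metabolism (7.5e-05 being the adjusted value of the smallest p the shuffles can give), 0.00084 for fatty acid synthesis and 0.00393 for heat shock proteins. Of the 10 widest total RNA rhythms, Rnaset2b (44.6-fold, adjusted p = 0.0375) has a near-identical paralog and is uncertain, and Crkl (22.1-fold) is described with translation efficiency. Cela3b (37.9-fold, adjusted p = 0.0377) and Cpb1 (31.9-fold, adjusted p = 0.0447) encode pancreatic enzymes, and their calls ended without the pools holding pancreatic transcripts (0.344 and 0.468). With single pools left out, Cela3b stayed called without a pool of ZT0, ZT10, ZT12 or ZT22, ZT4 replicate 2, ZT6 replicate 2, ZT8 replicate 1, ZT14 replicate 2 or ZT16 replicate 2 (otherwise 0.0528 to 0.0883), and Cpb1 without a pool of ZT0, ZT10 or ZT18, ZT4 replicate 2, ZT6 replicate 2, ZT8 replicate 1 or ZT16 replicate 2 (otherwise 0.0501 to 0.103). For Rnaset2b the adjusted p was 0.0559 to 0.0686 without any one pool of ZT6, ZT8, ZT10, ZT16, ZT18 or ZT20 or ZT4 replicate 1, and 0.246 without the pools holding pancreatic transcripts.

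Ribosome footprints followed the clock transcripts closely. In footprints Ciart cycled 115.8-fold (67.0 to 200.2), Nr1d1 59.1-fold (38.7 to 90.3) at ZT8.0, Dbp 50.2-fold at ZT11.0 and Arntl 23.3-fold at ZT23.1. Nr1d1 (chromosome 11, 98767932 to 98775333) went from 53.2 ± 2.32 RPKM (SD, n = 2) at ZT8 to 0.756 ± 0.0420 at ZT20. Per1 cycled 12.8-fold, Per2 11.6-fold, Tef 8.56-fold, Nr1d2 8.16-fold, Cry1 6.60-fold, Nfil3 5.48-fold, Bhlhe40 3.34-fold, Clock 2.16-fold, Cry2 2.12-fold and Hlf 1.90-fold. Again 15 of 16 clock genes were called (15 adjusted over the list alone), without Rora at 1.36-fold. All 17 tested clock-controlled outputs were called (17 adjusted over the list alone), Elovl3 with 30.3-fold, Noct with 18.8-fold and Nampt with 4.45-fold, and Rgs16 cycled 44.3-fold. Glucocorticoid targets moved by 2.60-fold (10 of 14 called), heat shock proteins by 1.85-fold (12 of 17 called), fatty acid synthesis by 1.51-fold (11 of 15) and xenobiotic metabolism by 1.41-fold (8 of 21), with 10, 13, 11 and 8 adjusted over the list alone and each with permutation adjusted p at or below 0.00225. The cold-inducible RNA-binding proteins cycled as transcripts and footprints, Cirbp 2.46-fold and 2.49-fold with peaks at ZT5.2 and ZT6.2, Rbm3 2.72-fold and 3.61-fold with peaks at ZT12.6 and ZT12.7. The Cirbp transcript call ended without the pools holding pancreatic transcripts (0.0705), with the range still at 1.21 log2. Transcripts and footprints also cycled for Cyp7a1, the limiting enzyme of bile acid synthesis (3.33-fold and 3.12-fold, at ZT15.9 and ZT15.5). Alb, the main plasma protein, at 1.37-fold and 1.43-fold, missed the minimum fold, and the reinitiation factors Denr and Mcts1 were not called in either assay.

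In footprints 1573 genes (16.7%) were called over 24 libraries, 89 of them by at least 4-fold, with a median fold of 1.76, 718 peaking in the light and 855 in the dark. Both assays called 1038 genes, where independent lists of these sizes would share 248.8. A further 456 were called in total RNA without footprints and 535 in footprints without total RNA, which by itself is no test of a difference between the assays. Of the 10 widest footprint rhythms, 7 encode pancreatic enzymes (Ctrb1 158.0-fold, Try4 116.5-fold, 2210010C04Rik 106.1-fold, Cela3b 66.2-fold, Cpb1 64.2-fold, Pnlip 59.4-fold and Cpa1 48.9-fold). They stood high in 6 of the 24 pools. Without those pools 1426 genes were called in total RNA and 1439 in footprints.

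**Figure D2:**
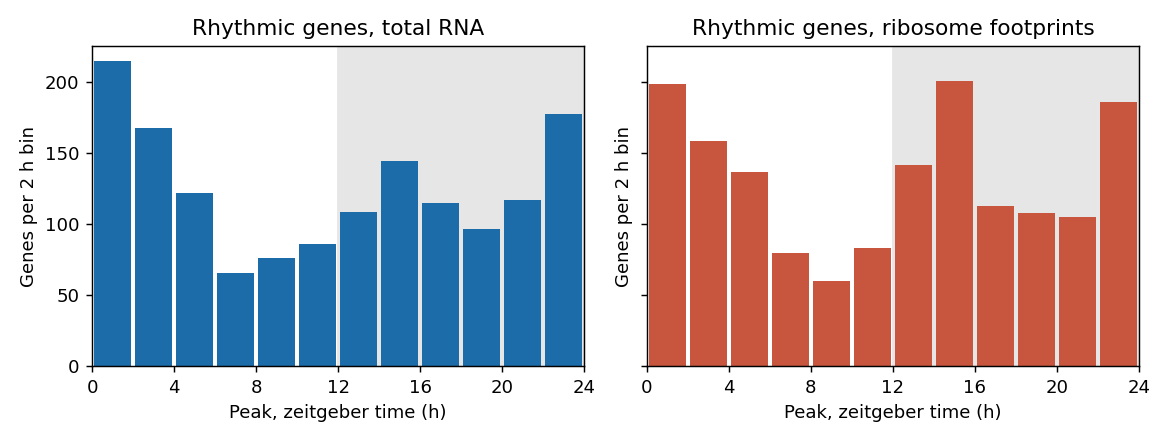
Number of genes called rhythmic per 2 h of fitted peak time (zeitgeber time in h), for total RNA and ribosome footprints, with darkness shaded. Of the called genes 761 in total RNA and 855 in footprints peak in the dark.

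No delay or change of amplitude between transcripts and footprints was detected over the rhythmic genes. Over the 1038 genes called in both assays the median delay was 0.005 h, with quartiles of -0.50 and 0.52 h, and 93.6% of genes peaked within 2 h in both. Arntl peaked at ZT23.1 in both assays, Nr1d1 at ZT8.1 and ZT8.0, and Per2 at ZT15.6 and ZT15.7. The median log2 ratio of footprint to transcript amplitude was 0.01, with quartiles of -0.15 and 0.16. Swapping assays within pools gave a median as far from 0 with a permutation p of 0.95 for the delay and 0.65 for the amplitude ratio (100 draws).

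Translation efficiency cycled in 35 genes, and in 305 when footprints were paired with total RNA by lysate pool (34 shared). Mitochondrially encoded respiratory chain subunits peaked in efficiency early in the dark, mt-Nd1 by 2.50-fold (ZT14.2), mt-Co3 by 2.42-fold, mt-Nd4 by 2.33-fold, mt-Cytb by 2.15-fold and mt-Co2 by 2.11-fold. Ftl1, the ferritin light chain, had a fitted peak at ZT0.5 with 2.40-fold (limma adjusted p = 0.048, paired 0.0203). Its footprints read 963 and 924 RPKM in the pools of ZT0, below those of ZT22 (2245 and 2229) and ZT4 (1497 and 2222). The fitted peak thus lies in a dip that the 24 h curve passes over. Histone H4 genes Hist1h4j (6.13-fold), Hist1h4c (2.70-fold) and Hist1h4h (2.56-fold) and Bloc1s1 (2.28-fold, ZT5.6), a subunit of a lysosome biogenesis complex, peaked in the light. Histone H4 genes and mitochondrially encoded genes have near-identical copies elsewhere in the genome, so their values are uncertain. Whether the fragments of mitochondrially encoded genes come from halted ribosomes was not tested. The widest of those named was Crkl, a signalling adaptor (17.3-fold, limma adjusted p = 0.00354). Washc1, a subunit of an actin-nucleating complex, cycled with it (4.35-fold, adjusted p = 0.00354). Their swing came from total RNA, where Crkl (chromosome 16, 17451987 to 17487434) read 26.4 to 625 RPKM in the 10 libraries of ZT12 to ZT20 and 7.71 to 16.9 in the other 14, against 10.4 to 17.6 in footprints. Washc1 read 13.6 to 47.0 in the former and 6.89 to 12.4 in the latter, against 5.17 to 11.1 in footprints. No core clock gene was called in efficiency (limma, 1 of 16 at an unadjusted p under 0.05), while 3 were in the paired fit. The median fold of the 35 was 1.68 and of the 305 it was 1.41. With time as a factor in place of the harmonic 39 genes were called in efficiency, 11 of them among the 35. That test did not call Hist1h4j, Hist1h4c, Bloc1s1 or Tmem243, and it called Fth1.

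These efficiency counts depended on single pools. The 35 became 18 without ZT2 replicate 2, 16 without ZT4 replicate 1, 23 and 22 without ZT6 replicates 1 and 2, 20 without ZT8 replicate 2, 20 and 17 without ZT18 replicates 1 and 2, and 17 without ZT20 replicate 1, and 0 without the 6 pools holding pancreatic transcripts (limma, 564 at an unadjusted p under 0.05 against 1041 with all pools, and 2 in the paired fit). The folds changed less than the counts when those 6 pools were left out. The 305 calls of the paired fit had a median range of 0.49 log2 with all pools and 0.48 log2 without them. They kept a median of 97.9% of their range along their own phase (quartiles 89.3% and 107.9%). By gene, the unpaired efficiency range with and without them was 4.11 and 4.97 log2 for Crkl, 2.12 and 2.42 for Washc1, 1.26 and 1.35 for Ftl1, 1.32 and 1.02 for mt-Nd1 and 1.11 and 0.82 for mt-Cytb. The 305 of the paired fit became 141 without ZT2 replicate 2, 129 without ZT4 replicate 1, 149 and 197 without ZT6 replicates 1 and 2, 180 without ZT8 replicate 2, 201 without ZT10 replicate 1, 194 without ZT12 replicate 2, 171 without ZT14 replicate 2, 151 and 198 without ZT18 replicates 1 and 2, and 155 without ZT20 replicate 1. Crkl, Washc1, Hist1h4h, Bloc1s1, mt-Nd1, mt-Co3 and mt-Co2 stayed called when any one pool was left out. The mt-Nd4 call ended without ZT2 replicate 2 (adjusted p = 0.0665), ZT4 replicate 1 (0.0542) or ZT12 replicate 1 (0.0572). That of Hist1h4j ended without ZT2 replicate 2 (0.0728), ZT4 replicate 1 (0.0801), ZT6 replicates 1 (0.0565) and 2 (0.057), ZT12 replicate 1 (0.0526), ZT18 replicates 1 (0.0672) and 2 (0.085) or ZT20 replicate 1 (0.0551). The Ftl1 call was kept only without a pool of ZT0, ZT16 replicate 1 or ZT20 replicate 2, and otherwise reached 0.0507 to 0.107. The Hist1h4c call was kept without a pool of ZT0, ZT10, ZT16 or ZT22, ZT4 replicate 2 or ZT8 replicate 2 (otherwise 0.0543 to 0.115). The mt-Cytb call was kept without a pool of ZT0, ZT10, ZT18 or ZT22, ZT4 replicate 2, ZT8 replicate 1, ZT16 replicate 1 or ZT20 replicate 2 (otherwise 0.0551 to 0.0905).

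Ferritin and mitochondrially encoded genes cycled in footprints without a called cycle in total RNA. Footprints of Fth1 (chromosome 19, 9980598 to 9985098), the ferritin heavy chain, cycled 2.44-fold (1.71 to 3.47, adjusted p = 0.00124) from 305.8 ± 117.6 RPKM (SD, n = 2) at ZT12 to 1383 ± 142.9 at ZT22, against 1.06-fold (0.963 to 1.18) in total RNA. Ftl1 (chromosome 7, 45457944 to 45459884) cycled 2.60-fold (1.86 to 3.64, adjusted p = 0.000383) against 1.10-fold (0.956 to 1.26). Like those of Ftl1, Fth1 footprints dipped at ZT0 (553 and 488 RPKM in its pools), between ZT22 and ZT4 (902 and 1025). The 24 h curve does not describe this dip. Ferritins store iron, and both genes have near-identical pseudogenes, so their values are uncertain. The difference between assays was tested by the interaction, which missed the threshold for Fth1 (adjusted p = 0.061) and passed it in the paired fit (0.0276). Without ZT0 replicate 1 (0.0257), ZT0 replicate 2 (0.0165) or ZT10 replicate 1 (0.0487) it passed unpaired. The transcription factor Deaf1 cycled 1.76-fold in footprints and 1.08-fold in total RNA, with an interaction adjusted p of 0.148, and 0.0205 paired, and its footprint call ended without the pools holding pancreatic transcripts (0.106, range 0.59 log2 against 0.82).

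Genes rhythmic in footprints and efficiency with a total RNA adjusted p of at least 0.05 numbered 7: Ftl1, mt-Co2, mt-Co3, mt-Cytb, mt-Nd1, mt-Nd4 and Tmem243, a membrane protein (1.59-fold, ZT19.5). The paired fit counted 27, adding among its 10 smallest p values Deaf1, Cebpe, Nfyb, Slc6a6 and Srek1, of which Nfyb was called unpaired without ZT0 replicate 2 (0.0318) or ZT22 replicate 1 (0.034). The 27 became 13 without ZT4 replicate 1, 15 without ZT6 replicate 1, and 16 without ZT8 replicate 2 or ZT18 replicate 1. The 7 became 12 without ZT0 replicate 1, 4 without ZT2 replicate 2, ZT4 replicate 1, ZT6 replicate 1, ZT8 replicate 2, ZT12 replicate 1 or ZT20 replicate 1, 3 without ZT6 replicate 2 or ZT16 replicate 2, and 0 without the pools holding pancreatic transcripts. The Tmem243 efficiency call (adjusted p = 0.0292) ended without ZT6 replicate 2 (0.098), ZT8 replicates 1 (0.0608) and 2 (0.0663), ZT10 replicate 1 (0.061), ZT18 replicates 1 (0.113) and 2 (0.058) or ZT20 replicate 1 (0.0672).

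Several groups of the translation machinery, and the mitochondrially encoded genes, cycled in footprints. Whether reads shared with copies elsewhere in the genome moved these values was not tested. Ribosomal protein footprints cycled as a list by 1.57-fold (1.19 to 2.08) with a peak at ZT14.2 (permutation adjusted p = 0.0371), against 1.17-fold (1.08 to 1.26) at ZT19.0 in total RNA (0.00905). Of 76 tested, 47 were called in footprints (51 adjusted over the list alone) and 5 in total RNA (5 adjusted over the list alone). This contrast comes with the minimum fold, as 56 and 54 had an adjusted p under 0.05. Examples are Rps6 at 1.76-fold and 1.16-fold and Rps27a at 1.93-fold and 1.11-fold. The efficiency of the list had a range of 1.54-fold with an adjusted p of 0.091, so the difference between assays was not called for the list. By gene, efficiency was called for 0 over all genes (limma, 58 at an unadjusted p under 0.05), 3 in the paired fit, and 56 and 49 adjusted over the list alone. Other translation factors with a terminal oligopyrimidine tract (TOP, a 5′ mRNA motif shared with ribosomal proteins) cycled 1.58-fold in footprints (adjusted p = 0.0164, 11 of 19 called, 11 adjusted over the list alone) and 1.06-fold in total RNA (0.042, 0 called by limma, 0 adjusted over the list alone, 12 at an unadjusted p under 0.05), with efficiency at 1.49-fold (1.17 to 1.90, adjusted p = 0.0499, 0 genes called by limma, 14 at an unadjusted p under 0.05 and 12 adjusted over the list alone, 2 and 13 in the paired fit). Elongation factor Eef1b2 cycled 2.13-fold in footprints and 1.06-fold in total RNA, and Rack1, a protein of the small subunit, 2.02-fold and 1.28-fold. Of 12 mitochondrially encoded genes, 12 were called in footprints and 0 in total RNA (12 and 0 adjusted over the list alone, 2 in total RNA at an unadjusted p under 0.05, limma), with the list at 2.16-fold (1.67 to 2.78) around ZT14.7 (adjusted p = 7.5e-05) against 1.16-fold (0.404) and efficiency at 2.11-fold (1.45 to 3.06, adjusted p = 0.0223, 5 genes called and 12 adjusted over the list alone, 7 and 10 in the paired fit). Ribosome biogenesis genes, such as the nucleolar protein Gnl3 (2.03-fold and 1.65-fold), cycled 1.23-fold in both assays (adjusted p = 0.0158 and 0.0142, 9 and 7 of 26 called and as many adjusted over the list alone).

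The ribosomal protein footprint call ended without ZT2 replicates 1 (adjusted p = 0.0602) and 2 (0.0573), ZT4 replicate 1 (0.0696), ZT12 replicate 2 (0.0652), ZT14 replicates 1 (0.0694) and 2 (0.0558), ZT16 replicate 1 (0.0599), ZT18 replicate 2 (0.0567) or ZT22 replicate 2 (0.057), and without the pools holding pancreatic transcripts (0.214). The ribosomal protein efficiency was called without ZT0 replicate 1 (0.0435), as was that of Rack1 (0.0495) and Eef1b2 (0.0281, and 0.0462 without ZT8 replicate 1). The TOP efficiency call was kept only without a pool of ZT0, ZT6 replicate 2, ZT8 replicate 1 or ZT12 replicate 1, and otherwise reached 0.0518 to 0.101, as the TOP total RNA call was kept without a pool of ZT0, ZT6, ZT8 or ZT18, ZT2 replicate 1, ZT4 replicate 1, ZT10 replicate 1, ZT20 replicate 1 or ZT22 replicate 2 (otherwise 0.0501 to 0.125). Without the pools holding pancreatic transcripts the adjusted p was 0.0747 for Eef1b2 footprints, 0.124 for TOP footprints, 0.232 for TOP efficiency and 0.232 for mitochondrially encoded efficiency. The ranges were 0.90, 0.54, 0.46 and 0.78 log2 against 1.09, 0.66, 0.58 and 1.08 with all pools.

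**Figure D3:**
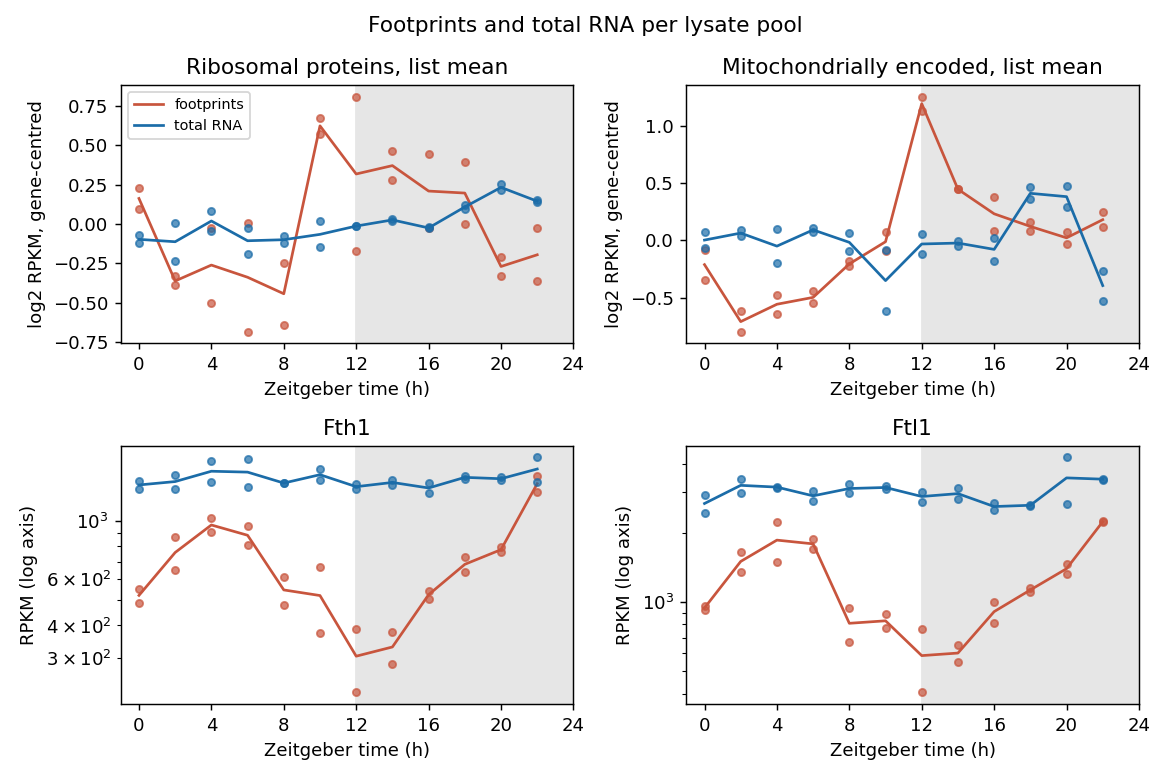
List means of ribosomal proteins and mitochondrially encoded genes (log2 RPKM, gene-centred) and RPKM (log axis) of Fth1 and Ftl1 against zeitgeber time in h, with a point per lysate pool, lines through the means of the 2 pools, and darkness shaded. Footprints swing more widely than total RNA in each panel, with Fth1 footprints lowest at ZT12 and highest at ZT22.

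The iron homeostasis list moved in total RNA (1.20-fold, adjusted p = 0.003) and not in footprints (1.06-fold, 0.567). Its efficiency moved by 1.15-fold around ZT3.6 (permutation adjusted p = 0.0223, and 0.05 without ZT18 replicate 2), with 3, 4 and 1 of 19 genes called in total RNA, footprints and efficiency and 3, 4 and 2 adjusted over the list alone. In the paired fit 3 were called in efficiency, and 6 adjusted over the list alone. Efficiency cycles were also called for xenobiotic metabolism (1.08-fold, adjusted p = 0.0293), endoplasmic reticulum chaperones with the unfolded protein response (1.07-fold, 0.0076), secreted plasma proteins (1.07-fold, 0.0401), endothelial markers (1.13-fold, 0.0072), stellate cell and fibroblast markers (1.21-fold, 0.0076) and, with the largest fold of any list, pancreatic acinar genes (2.82-fold, 0.0293, 0 of 9 genes called by limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05), so that 9 of 30 lists cycled in efficiency. The pancreatic fold rests on values near 0, as most members read close to the pseudocount of 0.1 outside the pools holding pancreatic transcripts. The count of lists was 5 and 4 without ZT18 replicates 1 and 2, and 2 with ratios of time point means in place of pool ratios. It was 5 without the pools holding pancreatic transcripts, where xenobiotic metabolism (0.0816) and plasma proteins (0.0915) were lost. The xenobiotic call ended without ZT8 replicate 2 (0.0562), ZT10 replicate 1 (0.0746), ZT18 replicates 1 (0.0521) and 2 (0.0516), ZT20 replicate 2 (0.0567) or ZT22 replicate 2 (0.0512). The call of plasma proteins was kept without a pool of ZT0, ZT4 or ZT16, ZT2 replicate 2, ZT6 replicate 1, ZT8 replicate 1, ZT12 replicate 1 or ZT14 replicate 1, and otherwise reached 0.0505 to 0.0777.

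Many sterol, bile acid and glucose genes cycled while the means of their lists, with the exception of cholesterol synthesis footprints, were not called. Members that peak at different hours can cancel in such a mean. In total RNA 9 of 24 cholesterol, 8 of 16 bile acid and 5 of 19 glucose genes peaked within 3 h of their list. An adjusted p under 0.05 (limma) was reached by 14, 14 and 13 of them. These 14, 14 and 13 are counted among all tested members of each list. Cholesterol synthesis had 7 and 10 of 24 genes called in total RNA and footprints, among them Pmvk (2.47-fold and 2.86-fold) and Hmgcs1 (2.09-fold and 2.17-fold), with the list at 1.18-fold (permutation adjusted p = 0.116) and 1.20-fold (0.0473). The footprint call of the list was kept only without a pool of ZT8, ZT0 replicate 1, ZT4 replicate 2, ZT10 replicate 2 or ZT18 replicate 1 (otherwise 0.0511 to 0.106). Bile acid metabolism had 8 and 9 of 16 called, among them the transporter Abcb11 (1.96-fold and 2.09-fold) and the sterol hydroxylase Cyp8b1 (2.75-fold and 2.56-fold), with the list not called (0.151 and 0.145). Glucose and glycogen metabolism had 11 and 10 of 19, led by glycogen synthase Gys2 (3.38-fold and 3.46-fold) and Ppp1r3c (5.65-fold and 5.59-fold), and PPARA targets 4 and 5 of 20, led by Pdk4 (6.59-fold and 8.32-fold), without a list call (0.176 and 0.232; 0.385 and 0.567). Immediate early genes had 2 and 4 of 10, led by Egr1 (6.75-fold and 11.5-fold), and tRNA synthetases 2 and 2 of 20, among them Cars (1.61-fold and 1.79-fold), also without a list call (0.0878 and 0.051; 0.241 and 0.567). In these 6 lists the counts adjusted over the list alone were the same.

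Several groups had small list folds, and some were called in 1 assay or in none. Nuclear-encoded subunits of oxidative phosphorylation had a list fold of 1.14-fold in total RNA (permutation adjusted p = 0.00167, 1 of 71 called) and 1.09-fold in footprints (0.051, 0 called, 36 at an unadjusted p under 0.05, limma), the proteasome of 1.06-fold (0.0842, 0 of 30, 18 at an unadjusted p under 0.05) and 1.10-fold (0.00133, 1 called, Psmd11), and mitochondrial ribosomal proteins of 1.08-fold (0.0842, 2 of 58) and 1.05-fold (0.291, 1 called, Mrpl34 at 1.57-fold). The mRNAs with regulatory upstream reading frames (uORFs) moved by 1.19-fold (0.001, 4 of 9 called, among them Atf5 at 2.89-fold) and 1.12-fold (0.0325, 3 called). That footprint call ended without ZT12 replicate 1 (0.069), ZT14 replicate 1 (0.0675) or ZT22 replicates 1 (0.059) and 2 (0.07). Endoplasmic reticulum chaperones and genes of the unfolded protein response, taken as 1 list, were not called in total RNA (0.544) or footprints (0.305). Of these 19 genes 3 and 5 were called (4 and 7 adjusted over the list alone), led by Trib3 (5.29-fold and 5.69-fold). Secreted plasma proteins were not called as a list (0.215 and 0.624), with 1 and 0 of 28 genes called (10 and 6 at an unadjusted p under 0.05). Nor was the acute phase list, whose fold was wide and uncertain (1.89-fold, 0.917 to 3.89, and 1.85-fold, 0.877 to 3.90, adjusted p 0.296 and 0.377), with 2 and 2 of 15 genes called (1 and 0 adjusted over the list alone), Saa4 by 2.10-fold and 1.97-fold. In the other groups of this paragraph the numbers adjusted over the list alone were the same as over all genes. The Psmd11 fold missed the minimum without a pool of ZT12 or ZT22, ZT4 replicate 2, ZT6 replicate 1, ZT10 replicate 1, ZT14 replicate 1, ZT16 replicate 2 or ZT20 replicate 2 (adjusted p 1.51e-06 to 2.01e-05 over all pools left out). The Saa4 footprint call (0.0214) ended without ZT16 replicate 1 (0.0566) or 2 (0.0565), and without the pools holding pancreatic transcripts neither Saa4 call was kept (0.0846 in total RNA, 0.135 in footprints, with ranges of 0.92 and 0.90 log2 against 1.07 and 0.98).

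Markers of other cell types were measured to see whether tissue make-up moved with time. Endothelial markers moved by 1.22-fold in total RNA (permutation adjusted p = 0.00624) and 1.11-fold in footprints (0.0433), with 0 of 11 called in either (0 adjusted over the list alone, 7 and 4 at an unadjusted p under 0.05, limma). The footprint call was kept without a pool of ZT0, ZT6 or ZT8, ZT2 replicate 2, ZT4 replicate 2, ZT10 replicate 2, ZT16 replicate 2, ZT18 replicate 1 or ZT20 replicate 2 (otherwise 0.0536 to 0.0903). Stellate cell and fibroblast markers moved by 1.18-fold (0.0292, 1 of 10 called, Pdgfrb at 1.63-fold) and 1.19-fold (0.0196, 3 called). Their total RNA call ended without ZT12 replicates 1 (0.0539) and 2 (0.0586), ZT20 replicate 2 (0.0504) or ZT22 replicate 2 (0.0648). Macrophage and Kupffer cell markers (0.296 and 0.602), red blood cell genes (0.218 and 0.292) and leukocyte markers (0.803 and 0.82) were not called as lists, with 0 and 1 of 12, 0 and 1 of 4 and 1 and 1 of 5 genes called and 0 and 1, 0 and 1 and 0 and 0 adjusted over the list alone (9 and 4, 1 and 1 and 1 and 1 at an unadjusted p under 0.05). Of the cholangiocyte markers, too few for a list test, Sox9 cycled 2.89-fold and 3.03-fold (in total RNA not called with time as a factor) and Spp1 was not called.

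Pancreatic acinar genes stood high in 6 of the 24 pools. In ZT2 replicates 1 and 2, ZT4 replicate 1, ZT6 replicate 1, ZT8 replicate 2 and ZT16 replicate 2 the list mean in total RNA was 3.85 to 6.08 log2 above its average, against -2.75 to 0.26 in the other 18. The digestive enzyme Ctrb1 had a median of 65.2 RPKM in total RNA of those pools and 0.109 in the others, and the same pools stood apart for 9 of 9 tested members in both assays. As a list they cycled in footprints (49.9-fold, 6.41 to 388.3, permutation adjusted p = 0.0164, 9 of 9 called) and not in total RNA (19.8-fold, 0.0848, 4 of 9 called, 7 adjusted over the list alone). Without the 6 pools the footprint range was 2.85 log2 (adjusted p = 0.00072) and the total RNA range 0.80 log2 (0.537). In the other 18 pools most members read near the pseudocount of 0.1, such as Pnlip with medians of 0.0605 RPKM in total RNA and 0.163 in footprints. Cela1 (9.94 in total RNA) and Cela2a (0.596) stood above it. Ranges and ratios in those pools are thus mostly of values near 0. The total RNA list was called without ZT6 replicate 2 (0.0484) or ZT16 replicate 2 (0.0141), and the efficiency call ended without ZT6 replicate 2 (0.0542), ZT18 replicate 1 (0.0636) or ZT18 replicate 2 (0.0704). As 5 of the 6 pools fell at ZT2 to ZT8, they lie at the hours when ribosomal protein and mitochondrially encoded footprints were low.

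**Figure D4:**
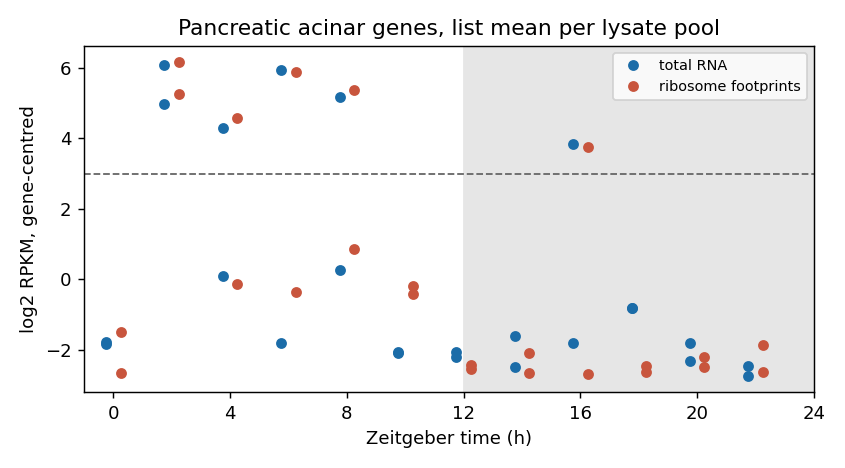
List mean of pancreatic acinar genes (log2 RPKM, gene-centred) against zeitgeber time in h, with a point per lysate pool and assay, darkness shaded, and a dashed line at 3 log2 as the boundary used. The 6 pools above the line stand between 3.85 and 6.08 in total RNA.

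Some lists were called once a pool was left out. In total RNA these were cholesterol synthesis (without ZT8 replicate 1, permutation adjusted p = 0.0442), tRNA synthetases (ZT14 replicate 1, 0.0357), the proteasome (ZT14 replicate 1, 0.0154), mitochondrial ribosomal proteins (ZT8 replicate 1, 0.0183, and ZT14 replicate 1, 0.0427) and immediate early genes (ZT0 replicates 1, 0.0395, and 2, 0.0453). In footprints they were oxidative phosphorylation (ZT0 replicates 1, 0.0348, and 2, 0.0399, ZT10 replicate 2, 0.0185, ZT16 replicates 1, 0.0316, and 2, 0.0313) and immediate early genes (ZT0 replicates 1, 0.0335, and 2, 0.0399, ZT8 replicate 1, 0.0414, ZT12 replicate 2, 0.0368, ZT16 replicate 2, 0.033, ZT20 replicate 2, 0.0402). In efficiency they were clock outputs (ZT0 replicate 2, 0.0145, ZT6 replicate 2, 0.0199), cholesterol synthesis (ZT10 replicate 2, 0.0478), PPARA targets (ZT0 replicate 1, 0.0318, ZT8 replicate 1, 0.0257) and glucose metabolism (ZT0 replicate 2, 0.0314, ZT10 replicate 2, 0.00848). Without the pools holding pancreatic transcripts, footprint calls were also lost for cholesterol synthesis (0.107), uORF-regulated mRNAs (0.0622), endothelial markers (0.0578) and stellate cell markers (0.107), and total RNA calls for TOP factors (0.0776) and stellate cell markers (0.0776). The ranges were 0.28, 0.17, 0.14 and 0.23 log2 against 0.26, 0.16, 0.14 and 0.25 with all pools in footprints, and 0.09 and 0.25 against 0.08 and 0.24 in total RNA.

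Mean translation efficiency differed more between genes than over the day. Relative to the median gene, it spanned 6.24-fold from the 5th to the 95th percentile (-1.53 to 1.11 log2), and mean footprints and mean total RNA correlated across genes with r = 0.935, genes not being independent replicates. Among 5503 well-expressed genes the highest were the immunophilin Fkbp1a with 2.99 ± 0.29 log2 (SD, n = 24 pools), Zfp36l1 with 2.86, the proton pump subunit Atp6v0c with 2.76, Hcfc1r1 with 2.68 and Ubl5 with 2.67. The lowest were ENSMUSG00000075043 with -5.00 ± 2.58 (SD, n = 24 pools, footprints 4.57 ± 6.46 RPKM at ZT8 and 0 at ZT12, so uncertain), BC005537 with -4.57, the co-chaperone Bag1 with -3.84, Cenpb with -3.45 and Dnajc14 with -3.43. By list, mean efficiency was low for ribosomal proteins (median -0.91, 9 of 76 above the median gene), mitochondrially encoded genes (-1.58) and uORF-regulated mRNAs (-1.39), and high for 10 lists, among them xenobiotic metabolism (0.89), secreted plasma proteins (0.58), PPARA targets (0.58) and oxidative phosphorylation (0.51). These 13 calls used camera with a preset correlation, and 0 of them held with an estimated correlation (smallest adjusted p = 0.196 with an estimated correlation).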

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

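The tests of the pools with pancreatic transcripts, of the pancreatic genes themselves, of total RNA libraries made apart and of other arrangements of the samples were chosen only after the results were seen, and those of coding length, abundance, GC content and read depth before their own result was seen.

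These results stand here because footprints and total RNA differed in their daily course by a test of the difference itself, the interaction for genes and a permutation test of the footprint to total RNA ratio for lists. Translation efficiency was rhythmic in 35 genes, and 7 genes were rhythmic in footprints and efficiency with no called transcript rhythm. Among lists the efficiency moved by 1.49-fold for TOP translation factors, 1.15-fold for iron homeostasis, 1.08-fold for xenobiotic metabolism, 1.07-fold for endoplasmic reticulum chaperones with the unfolded protein response (1.065), 2.11-fold for mitochondrially encoded genes, 1.07-fold for secreted plasma proteins, 1.13-fold for endothelial markers, 1.21-fold for stellate cell and fibroblast markers and 2.82-fold for pancreatic acinar genes. The pancreatic value rests on readings near 0 in most pools. Chance was set against the gene counts with 100 arrangements each, the real one included. For efficiency, swapping assays within pools gave as many calls in 1 of 100, the real arrangement itself, with 0 as the highest other against 35, and for footprint rhythms with rhythmic efficiency alone in 1 of 100, with 0 against 7. Such a swap can add a gene's constant difference between assays to its scatter, which by itself lowers the number of calls. The swaps are therefore weak evidence on chance for the 35 and the 7. With pools paired and time points reordered, as many calls came in 1 of 100, with 1 as the highest other against 305. Reordering gave 1 of 100 for total RNA (highest other 2, real 1494) and for footprints (highest other 11, real 1573), so chance orders can be excluded for these counts. For lists with shifted mean efficiency it was 1 of 100, with a highest other of 12 and a median of 7 against 13. That swap, made in a random part of the pools, leaves part of the real difference between assays in place. It therefore cannot tell how many lists chance alone gives. The peak delay (0.005 h, highest other 0.129 h, 95 of 100 as large) and the amplitude ratio (0.01 log2, highest other 0.05, 65 of 100) are sizes for which chance cannot be excluded.

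Pancreatic acinar genes stood high in 6 of 24 pools. A daily rhythm shared by the livers was argued against as the source of the 6 high pools by the pair of pools at ZT6, whose list means differed by 7.71 log2 in total RNA, while a rhythm in the other pools stays open, since without the 6 the list still cycled in footprints (2.85 log2, adjusted p = 0.00072). Pancreatic tissue in those pools is a candidate explanation that stays open. The pools were picked on total RNA, and 9 of 9 tested members picked out the same pools in footprints. Ctrb1 had a median of 174 RPKM in footprints of those pools and 0.247 in the others. Both assays shared the lysate, so any source of the transcripts in it would give this agreement. The agreement thus cannot tell pancreatic tissue from another source. Of the members, Cela1 was also measured in the other pools, at 4.63 to 17.0 RPKM in total RNA. The labels name no sort or gate before lysis, and a different source of the transcripts was not tested.

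Ribosomal protein footprints peaked early in the dark. Short coding length and high abundance were argued against, since the list's range of 0.65 log2 lay at percentile 100 of 10000 random lists matched on both, whose median was 0.12 and highest 0.33. The pools with pancreatic transcripts stay open: without them the range was 0.53 ± 0.25 log2 (SE, adjusted p = 0.214), an error too wide to part the full 0.65 log2 from a much smaller range, and the call ended with fewer pools. A daily rhythm of translation, which the design names, also stays open.

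Efficiency calls of the paired fit peaked at opposite times, 125 at ZT2 to ZT8 with a median coding length of 697.5 bases and 111 at ZT14 to ZT20 with 1245 bases. Coding length and GC trends of single libraries were argued against as the whole cause, as 265 of the 305 calls were kept with the trends removed. The pools with pancreatic transcripts were argued against as the whole cause as well, by the ranges and not by the count of calls. Without them 2 calls were left, as few as in 5 of 99 random sets of 6 pools (median 20, range 1 to 438), which does not decide. Leaving out 6 partner pools of the same time points left 38, but both ZT2 pools, which hold pancreatic transcripts, were among these partners. The 305 calls, picked with all pools, kept a median of 97.9% of their range along their own phase (quartiles 89.3% and 107.9%, random sets 91.1% to 110.7%). Total RNA libraries of ZT12 to ZT20 made apart from the others stay open, as 66.9% of the calls had an adjusted p under 0.05 in total RNA and 60.3% in footprints, neither far enough to decide. Lower depth of dark-phase total RNA also stays open, since thinning kept 78 calls but costs power in the light as well, and neither can be told apart here from a daily rhythm of translation.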

How the results depend on the processing

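The voom, thinning, shallowest-library, pancreatic-pool and coding length and GC alternatives, and combinations of the pool block with these or with a minimum fold of 1.5, were chosen only after the data were seen. Counts of rhythmic genes in total RNA and footprints stayed within 1.5 times under every alternative run except a mean RPKM of at least 5 (903 and 971, where fewer genes were tested), no minimum fold (4072 and 4253) and a minimum fold of 2 (475 and 500). The delay and amplitude ratio stayed within the spread under all alternatives run.

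Efficiency results moved most. The 35 genes and the 7 with footprint rhythm alone became 65 and 14 at a mean RPKM of at least 5, and 11 genes were left at an adjusted p under 0.01. Time as a factor gave 39 genes, with 11 of the 35 among them. Voom weights gave 11 for the latter count, thinning 14 for the former, the shallowest library left out 17, the pancreatic pools left out 0 and 0 (limma), and the coding length and GC trend removed 68 and 4. The cause was not tested, except where fewer libraries or reads entered. With the lysate pool as replicate block (pairing) they were 305 and 27, and 102 and 25 with a minimum fold of 1.5. The paired counts were 89 and 14 after thinning, 198 and 24 without the shallowest library, 2 and 0 without the pancreatic pools, and 485 and 30 with trends removed. The replicate number as a replicate block changed no count beyond 1.5 times. Among named results it ended 4 calls near the threshold (Ftl1 in efficiency, Cpb1 and Cela2a in total RNA, Cd74 in footprints) and added 1 (Eef1d in efficiency), and the pool block ended 0 calls of named genes and added 40. Replicate numbers share nothing across time points (median r 0.012 in total RNA and 0.015 in footprints, with 9 and 12 of 66 pairs above 0.1).

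Leaving out each pool gave 1415 to 1625 genes in total RNA, 1497 to 1666 in footprints, 16 to 52 in efficiency, 3 to 12 with footprint rhythm alone and 129 to 353 in the paired fit. Lists ranged over 12 to 16, 12 to 18 and 4 to 11 for total RNA, footprints and efficiency, and stayed at 13 for mean efficiency. Lists rhythmic in efficiency numbered 4 without the shallowest library, 5 without the pancreatic pools and 2 with ratios of time point means (no replicate block). Lists in footprints numbered 10 without the pancreatic pools. Mean efficiency was shifted in 8 lists at a mean RPKM of at least 5 and in 0 with an estimated correlation. Of 16388 results for named genes, 97.2% kept their status, called or not called, 287 lost a call and 164 gained one. Of 4140 for lists, 94.6% kept their status, 170 lost a call and 52 gained one, and none turned direction. Results not called in either setting count as kept, and most results come from single pools left out. The percentages are therefore not shares of calls that held. Total RNA of ZT18 replicate 2 held 3.86 M reads, and whether depth limits the efficiency calls stays open, as thinning to the lowest depth gave 14.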

Other observations

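The pool comparison below was chosen only after the data were seen. Within a time point, the difference in efficiency between the 2 pools moved together for ribosomal proteins and other TOP factors over the 12 time points (Pearson r = 0.956, permutation p = 3e-05, adjusted 9e-05, and Spearman rho = 0.958, permutation p = 2e-05, adjusted 6e-05, with r = 0.967 without the 2 farthest). For mitochondrially encoded genes it did not pass (r = -0.046, permutation p = 0.887, adjusted 0.887, and rho = 0.105, permutation p = 0.747, adjusted 0.747, with r = 0.257 without the 2 farthest). For iron homeostasis it did not pass after adjustment (r = 0.615, permutation p = 0.0339, adjusted 0.0508, and rho = 0.566, permutation p = 0.0586, adjusted 0.0879, with r = 0.461 without the 2 farthest). These are 3 relations of 1 family, adjusted together.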
